A study of Homo sapiens with 18 samples.

How the data were processed

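Tissue from dorsolateral prefrontal cortex was sequenced in 18 samples, 11 labelled control and 7 labelled schizophrenia. Per the labels' protocols, RNA was extracted, some replicate samples were homogenized dry, stranded libraries of polyadenylated RNA were made, and paired reads of 150 bases were sequenced. Which samples were homogenized dry is not stated, so this step could not enter a model. Per the submitters' processing notes Salmon 1.6.0 was used, a tool that assigns reads to transcripts by probability.

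The deposited table holds estimated counts per isoform, which are not whole numbers. Isoforms carry a locus number, an isoform number and a gene symbol. How the counts were scaled, which filters were applied before deposit and which genome build was used are not given in the sources used here. Because reads of overlapping isoforms are divided by an estimate, an isoform can receive 0 in one sample and many reads in another while the gene total stays steady, and this uncertainty is not in the counts. Isoform structures and repeated estimates per sample were not used here. Genes on the sex chromosomes are not analysed here.

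Isoform counts were summed per gene and rounded, and isoform counts were rounded on their own. Total counts lay between 45866112 and 102896709 per sample. Low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 10877 genes and 39598 isoforms, and library sizes were scaled with TMM factors. Genes and isoforms were tested with edgeR's quasi-likelihood F test (robust, no covariates) with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels give no batch, age, RNA quality or post-mortem interval per sample, so none of these could enter a model. Group differences in them cannot be told apart from the diagnosis. Standard errors of log2 fold changes came from the same F statistic. Isoform usage was tested with edgeR's diffSpliceDGE, with Simes p-values per gene, over 7762 genes with 36484 isoforms. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and the data.table package (1.17.8).

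Before the data were examined, 29 gene lists were fixed: presynaptic release, postsynaptic density, GABA receptors, voltage-gated channels, monoamine and acetylcholine signalling, cytoskeleton and axon, common and rare variant schizophrenia genes, splicing regulators, nuclear long non-coding RNAs, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis, heat shock, immediate early genes, metallothioneins, inflammation, complement, interferon response, blood, and markers of excitatory and inhibitory neurons, astrocytes, microglia, oligodendrocytes, their precursors, endothelium with pericytes, and white matter with subplate and meninges. Of 722 list genes, 477 were in the table and 476 were tested. The 26 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 on log2 CPM (prior count 3), and also with an estimated correlation, fry, and an exact permutation test of the list means per sample over 31824 splits. Camera compares a list with all other genes, while the permutation test asks whether the list mean differs between groups. Enrichment for isoform usage was tested with Fisher's exact test (one-sided) and with 10000 matched permutations of the mean rank (two-sided).

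Genes named in the text followed a rule also fixed before the data were examined: the 10 genes or isoforms with the smallest unadjusted p where fewer than 10 passed, up to 20 genes called for isoform usage, and from each list 2 to 4 measured members with the smallest unadjusted p. Here 4 were taken from every list, or all where fewer were measured, and that number was chosen after values had been seen. Some of these members are not described in the text. List members named for isoform usage were the first by p in their lists, except ENO1 among the glycolysis genes.

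All group tests are two-sided unless stated. The tests listed here were tried on simulated counts with 100 features changed per fold, and the other tests were not. For gene expression (10876 genes), 79% of 1.5-fold and 91% of 2-fold changes were recovered with 13 false calls among 183. For isoform expression (37973 isoforms), 20% of 2-fold and 72% of 4-fold changes were recovered with 1 false call among 93. For isoform usage (7676 genes), the planned test recovered 2% of 2-fold and 7% of 4-fold changes, with 74 false calls among 83, so its calls have no controlled error rate. It was kept as planned, and a quasi-likelihood test per isoform with the gene total as offset was added for that reason (15% and 59% recovered, 3 false among 77). Limma on log2 shares recovered 13% and 58% (3 false among 74), and limma's diffSplice 25% and 64% (55 false among 144).

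Of the gene symbols in the table, 10551 (96.9%) matched GENCODE 29, from which coordinates, transcript lengths and GC content were taken, and 10544 tested genes (96.9%) had a length and GC value. Both values were medians over all annotated transcripts of the symbol, not over the isoforms measured. Per library, slopes of log2 CPM deviations on GC content and log2 length were fitted. Other settings compared were RLE scaling, no filter, DESeq2, limma-voom with and without sample quality weights, surrogate variables (at most 3), the replicate number as a block, other usage tests and filters, and leaving out each sample. Settings added after seeing the data were the offset test, a usage test on isoforms with a count of 10 in 16 of 18 samples, permutation tests of list means and shares, the first principal component as a covariate, GC and length slopes as covariates (for lists also with an estimated correlation), and list means and shares under other settings and without each sample.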

Results

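The series measured RNA from post-mortem dorsolateral prefrontal cortex (Brodmann areas 8 and 9), a frontal region involved in working memory, with short-read sequencing of polyadenylated RNA. The labels give 11 control and 7 schizophrenia samples, and 1 table holds estimated read counts for 56163 isoforms of 10886 genes in all 18. Total counts per sample ranged from 60619257 to 89460558 in controls and from 45866112 to 102896709 in schizophrenia samples. A gene had a median of 3 isoforms in the table and at most 97, and 10444 isoforms stood at 0 in every sample. No pair of samples agreed within sampling noise, so each counted as 1 replicate. The labels do not state that each sample came from a separate donor, so p-values measure only the spread between these samples, which may be technical. Following the series title, the comparisons ask which genes, isoforms, isoform shares and gene groups differed between schizophrenia and control.

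The genes with the smallest p in the comparison of expression were ZNF385A, which encodes a zinc finger protein, and RAPGEF5, an exchange factor for Rap GTPases. ZNF385A stood at 100.7 ± 10.6 CPM (read counts scaled to an equal library total; mean ± SD) in the 11 control samples and at 134 ± 25.5 in the 7 schizophrenia samples, a log2 fold change of 0.41 (SE 0.094), with 6 of 7 schizophrenia samples above the control median. RAPGEF5 stood at 297 ± 36.2 CPM in controls and 238 ± 14.3 in schizophrenia (log2 fold change -0.32, SE 0.073), with 0 of 7 samples above the control median. RASL10A, a Ras-like small GTPase, stood at 29.5 ± 5.65 and 41.9 ± 5.27 CPM (0.51), and was above the control median in 7 of 7 samples. TRAPPC5 (0.37), ANTKMT (0.33), PHPT1 (0.27), NAT14 (0.22) and DPYSL4 (0.25) had higher estimates in schizophrenia, and TMPO, which encodes nuclear lamina proteins, a lower one (-0.33). SLC22A8, an organic anion transporter, had the largest log2 fold change of the 10 (3.64), at 0.212 ± 0.149 CPM in controls and 2.69 ± 5.98 in schizophrenia, and without the sample schizophrenia 5 it was 1.02.

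None of these differences passed: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 10877 genes, with 973 at an unadjusted p under 0.05 (438 higher, 535 lower) and a smallest adjusted p of 0.526. DESeq2 called 0 genes (1068 at an unadjusted p under 0.05, smallest adjusted p 0.0859 for RAPGEF5), and limma-voom called 0 (853). Genes at an unadjusted p under 0.05 with a higher estimate had a median transcript GC content of 58.6%, those with a lower estimate 43.9%, and all tested genes 49.4%. In GENCODE 29 on GRCh38, matched by symbol because the build behind the table is not given in the sources used here, ZNF385A lies on chromosome 12 (54369133 to 54391298), RAPGEF5 on chromosome 7 (22118238 to 22357144) and RASL10A on chromosome 22 (29312933 to 29319679).

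**Figure D1:**
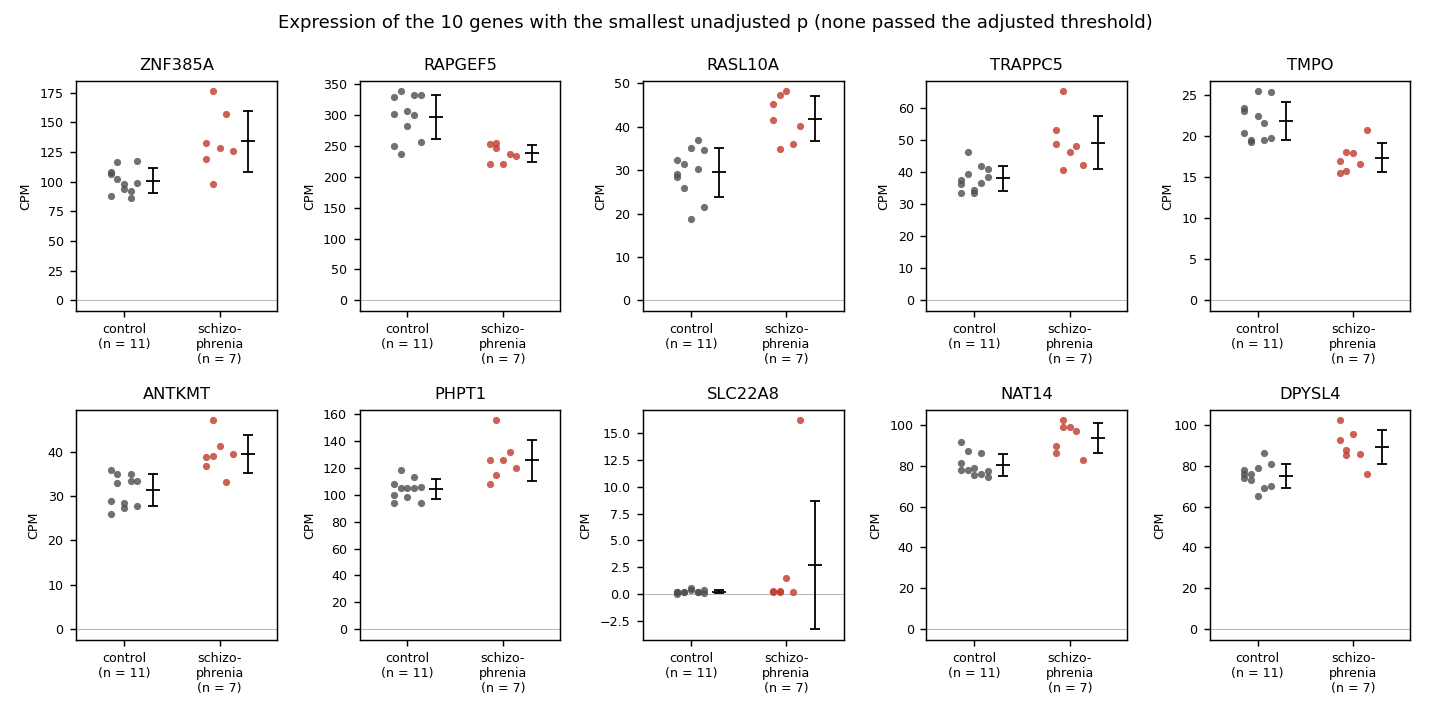
CPM (vertical axis) of the 10 genes with the smallest unadjusted p, in 11 control (grey) and 7 schizophrenia (red) samples; dots are samples and bars beside them the mean ± SD. RASL10A stood at 29.5 ± 5.65 CPM in control and 41.9 ± 5.27 in schizophrenia, and the wide bar of SLC22A8 rests on 1 schizophrenia sample.

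Synaptic genes, the subject of the series title, went both ways. Of 30 measured presynaptic release genes, 13 had a higher and 17 a lower estimate in schizophrenia, and 0 passed. SLC17A7, the main vesicular glutamate transporter of the cortex, stood at 1760 ± 125 CPM in 11 controls and 1954 ± 133 in 7 schizophrenia samples (log2 fold change 0.15, SE 0.053). The endocytic protein gene AMPH stood at 260.5 ± 26.8 and 229 ± 14.7 CPM (-0.18), with 0 of 7 samples above the control median, as for the synaptotagmin gene SYT11 (-0.49), and DOC2A had a higher estimate (0.12). Of 30 postsynaptic density genes, 15 had higher and 15 lower estimates: PSD3 (-0.70, SE 0.32), ANKS1B (-0.11) and the glutamate receptor gene GRM5 (-0.66) lower, and CACNG3, an AMPA receptor partner, higher (0.19). The mean log2 CPM of the presynaptic list differed by -0.044 (95% interval -0.21 to 0.12) and that of the postsynaptic list by -0.043 (-0.24 to 0.16), with camera adjusted p of 0.973 for both. Without the sample schizophrenia 7 these differences were 0.0051 and 0.0097. With GC and length slopes of the libraries as covariates both lists passed camera in the other direction, higher (presynaptic adjusted p 0.0346, postsynaptic 0.00515), but not with an estimated correlation (0.801 for both).

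Genes near common schizophrenia risk variants showed small differences. Of 28 measured, 11 had higher and 17 lower estimates, among them DGKZ, a diacylglycerol kinase (0.19, SE 0.079), IMMP2L (-0.26), FXR1 (-0.13) and the chloride transporter gene CLCN3 (-0.12). The list mean differed by -0.028 (95% interval -0.10 to 0.048; camera adjusted p 0.724). Of 8 genes tied to schizophrenia by rare coding variants, 6 had lower estimates, and HERC1, a ubiquitin ligase gene, stood at 27.4 ± 17.0 CPM in 11 controls and 14.95 ± 6.17 in 7 schizophrenia samples (-0.87, SE 0.37). SETD1A, a histone methyltransferase gene, had a higher estimate (0.13), and XPO7 (-0.085) and CUL1 (-0.062) lower ones. The mean of this list differed by -0.13 (-0.30 to 0.046; camera adjusted p 0.428). Of both lists, 0 genes passed, also adjusted over the list alone.

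Voltage-gated ion channel genes, which set the excitability of neurons, had lower estimates in 13 of 16 cases. KCNA2, a potassium channel gene, stood at 30.6 ± 20.3 CPM in 11 controls and 14.4 ± 6.43 in 7 schizophrenia samples (log2 fold change -1.09, SE 0.40), with 0 of 7 samples above the control median. CACNA2D3, a calcium channel subunit gene (-0.27), and SCN3A (-0.34) also had lower estimates. So did KCNJ3 (-0.16), an inward rectifier gene in this list whose channel is not itself voltage-gated. As a list the channel genes passed camera with a preset correlation of 0.01 (adjusted p 0.0209, lower), but not with an estimated correlation, where the adjusted p was 0.990. Their mean differed by -0.19 (95% interval -0.40 to 0.020; adjusted exact permutation p 0.850), and 0 members passed. With the GC and length slopes of the libraries as covariates the camera adjusted p was 0.559, and the call was also lost without control 6 or schizophrenia 1, 3 or 7 (highest adjusted p 0.134).

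Of 12 GABA receptor genes, 7 had lower estimates, among them GABRA4 (-0.43, SE 0.26), and the list mean differed by -0.066 (camera adjusted p 0.711). Among 16 excitatory neuron markers, SLC17A6 (-0.35) and the layer marker RORB (-0.41) had lower estimates, and SLC17A7 and NEUROD6 (0.27) higher ones. The mean of that list differed by 0.0037, while its median log2 fold change was -0.047 and camera pointed down (adjusted p 0.973). Of 17 inhibitory neuron markers 12 had higher estimates, with CALB1 (-0.37) and KCNC1 (-0.13) lower and PVALB (0.18) higher (mean difference 0.0098, camera adjusted p 0.973). Of 16 monoamine and acetylcholine signalling genes, CHRM1 (0.18) and PPP1R1B (0.28) had higher and CHRNA7 (-0.23) and CHRM3 (-0.27) lower estimates. Their mean differed by -0.019, their median was 0.038 and camera pointed up (adjusted p 0.973). None of the members of these 4 lists passed.

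All 18 measured astrocyte markers had higher estimates in schizophrenia. GLUL, the glutamine synthetase gene, stood at 1568 ± 570.1 CPM in 11 controls and 2054 ± 854 in 7 schizophrenia samples (log2 fold change 0.39, SE 0.25), and NDRG2 (0.33), RANBP3L (0.40) and FGFR3 (0.50) followed. The list passed camera with the preset correlation (adjusted p 0.0209, higher), with an adjusted p of 0.990 with an estimated correlation. Its mean differed by 0.27 (95% interval -0.36 to 0.89; adjusted exact permutation p 0.985), and 0 members passed. The camera adjusted p was 0.0574 with surrogate variables and 0.751 with GC and length slopes as covariates, and the call was lost without control 4, 7 or 11 or schizophrenia 1, 3 or 7 (highest adjusted p 0.416).

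Other glial and vascular marker lists did not pass camera without covariates. Of 19 myelin and oligodendrocyte genes, 18 had lower estimates, such as MBP (-0.33, SE 0.44), GALC (-0.072), UGT8 (-0.29) and MOBP (-0.30), with a list mean difference of -0.13 (95% interval -1.12 to 0.87; camera adjusted p 0.699). Of 11 oligodendrocyte precursor markers 10 had higher estimates, led by BCAN (0.33, SE 0.13), with PTPRZ1 (0.25), COL9A1 (0.31) and GPR17 (0.35) (mean difference 0.15, camera adjusted p 0.202). Among 9 microglial markers, SPI1 (0.14) and TREM2 (0.19) had higher and CD68 (-0.17) and C1QC (-0.17) lower estimates (mean difference -0.015, 95% interval -0.97 to 0.94, camera adjusted p 0.973). Of 14 endothelial and pericyte markers, PDGFRB (0.21) and ABCC9 (0.27) had higher and SLC2A1 (-0.14) and FLT1 (-0.20) lower estimates (mean difference 0.0031, camera adjusted p 0.973). All 7 white matter, subplate and meningeal markers had higher estimates, with OGN (1.23, SE 0.65), PTGDS (0.52), SLC6A13 (0.49) and TTR (1.64) leading (mean difference 0.47, 95% interval -0.31 to 1.27, camera adjusted p 0.202). Without schizophrenia 5, OGN was at 0.18 and the list mean difference at 0.19. With GC and length slopes of the libraries as covariates, the microglia (adjusted p 0.0128) and white matter lists (0.0360) passed camera as higher and the myelin list as lower (0.000126), but not with an estimated correlation (0.801 for each).

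Ribosomal protein genes had higher estimates in schizophrenia in 30 of 31 cases. RPL14 stood at 241 ± 26.2 CPM in 11 controls and 275 ± 27.3 in 7 schizophrenia samples (log2 fold change 0.19, SE 0.073), and RPL38 (0.20), RPS19 (0.22) and RPLP1 (0.18) were close to it in size. The list passed camera with the preset correlation (adjusted p 0.000171, higher), with an adjusted p of 0.990 with an estimated correlation. Its mean differed by 0.11 (95% interval -0.072 to 0.29; adjusted exact permutation p 0.850), and 0 members passed. Ribosomal protein genes have many near-identical pseudogenes, so the counts of single members are uncertain.

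Nuclear-encoded oxidative phosphorylation genes had 22 higher and 16 lower estimates among 38, with NDUFS3 (0.17), NDUFB9 (0.20) and ATP5F1D (0.23) higher and ATP5F1B (-0.14) lower (list mean difference 0.027, camera adjusted p 0.588). Of 19 glycolysis genes, GPI (0.15) and ENO1 (0.14) had higher and ENO2 (-0.14) and LDHB (-0.11) lower estimates (0.0070, 0.973). Splicing regulators had higher estimates in 24 of 37 cases, with RBFOX3 (0.22, SE 0.073), CELF1 (0.17), CLK4 (0.28) and SRSF5 (0.18) each above the control median in 7 of 7 schizophrenia samples. Their mean differed by 0.048 (95% interval -0.0036 to 0.099), with a camera adjusted p of 0.175, or 0.00424 with GC and length slopes as covariates (0.801 with an estimated correlation as well). Of 34 cytoskeleton and axon genes, ACTB, the beta-actin gene, stood at 2771 ± 180 CPM in 11 controls and 3209 ± 275 in 7 schizophrenia samples (0.21, SE 0.055), above the control median in 7 of 7. Adjusted over the list alone ACTB passed (edgeR adjusted p 0.0369), while over all genes its adjusted p was 0.531. DST (-0.62), ANK3 (-0.49) and NEFL (-0.19) had lower estimates (list mean difference -0.055, camera adjusted p 0.856). Among 6 nuclear long non-coding RNAs, SNHG14 stood at 38.8 ± 11.3 and 27.4 ± 2.78 CPM (-0.50) and passed adjusted over the list alone (edgeR adjusted p 0.0195) but not over all genes (0.531). MALAT1 (0.24), MEG3 (0.34) and NEAT1 (0.14) had higher estimates, and camera pointed down (adjusted p 0.973) although the list mean (0.036) and median (0.051) were above 0.

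Heat shock genes had lower estimates in 12 of 18 cases, among them DNAJA1 (-0.22, SE 0.077), DNAJB4 (-0.23), HSPA8 (-0.34) and HSPH1 (-0.13), with a list mean difference of -0.052 (camera adjusted p 0.267). Without control 8 that difference was 0.024. Of 18 immediate early genes 15 had higher estimates, with VGF (0.45, SE 0.17), PPP1R15A (0.15), BDNF (0.27) and KLF2 (0.38) leading (0.18, camera adjusted p 0.117, or 6.26e-06 with GC and length slopes as covariates and 0.801 with an estimated correlation as well). Among 13 inflammation and acute phase genes, FKBP5, a glucocorticoid-induced chaperone gene (-0.81, SE 0.33), and CD44 (-0.66) had lower and CCL2 (0.52) higher estimates (-0.12, camera adjusted p 0.856). SERPINA3, an acute phase inhibitor gene of that list, stood at 38.6 ± 122 CPM in controls and 3.78 ± 6.91 in schizophrenia (-3.39, SE 1.72), and without control 8 its log2 fold change was 1.05. Of 15 complement genes, CD46 (-0.14) and CD55 (-0.14) had lower estimates and CLU (0.20) a higher one (-0.079, camera adjusted p 0.711). CD59 had an estimate of -0.059 although 7 of 7 schizophrenia samples lay above the control median, and without control 8 it was 0.037. Interferon response genes OASL (0.68), OAS1 (0.48) and XAF1 (0.31) had higher estimates (0.14 over 15 genes, camera adjusted p 0.423). Lists of blood genes (HBB 1.05 with SE 0.57, CSF3R -0.037), metallothioneins (MT1G 0.19) and mitochondrially encoded genes had 2, 1 and 0 measured members and were not tested. None of these genes passed.

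**Figure D2:**
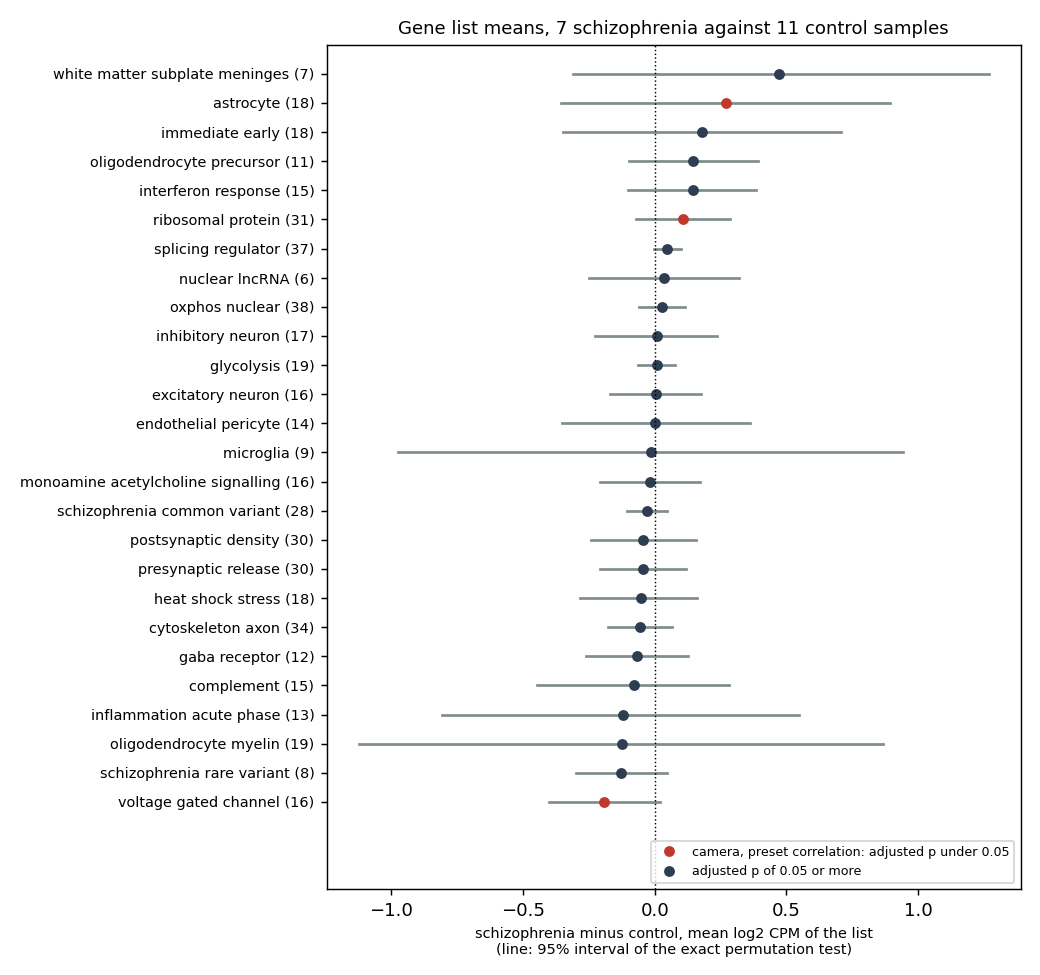
Difference in mean log2 CPM, schizophrenia minus control (horizontal axis), for the 26 gene lists tested, with the number of measured genes in brackets; dots are differences, lines 95% intervals of the exact permutation test, and red dots the 3 lists past camera with a preset correlation. Every interval crosses 0, including those of the ribosomal protein list (-0.072 to 0.29), the astrocyte list (-0.36 to 0.89) and the voltage-gated channel list (-0.40 to 0.020).

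Single isoforms were compared next, named by their locus, isoform number and gene in the table. MRFAP1 isoform PB.10622.168 stood at 41.2 ± 6.02 CPM in 11 controls and 27.1 ± 5.26 in 7 schizophrenia samples (log2 fold change -0.60, SE 0.12). CAPZA1 isoform PB.2056.6, of an actin-capping protein gene, stood at 7.15 ± 0.996 and 10.7 ± 1.65 CPM (0.59), and GRM2 isoform PB.8245.767, of a presynaptic glutamate receptor gene, at 14.1 ± 2.58 and 20.5 ± 2.58 CPM (0.54). Higher estimates were also found for BCAN isoform PB.2600.261 (0.85) and SDF4 isoform PB.39.27 (0.80), and lower ones for HSD17B4 isoform PB.14133.29 (-0.75), RAPGEF5 isoform PB.17804.19 (-0.33) and RINT1 isoform PB.18988.20 (-1.16). TIAL1 isoform PB.25937.111 stood at 1.56 ± 1.19 CPM in controls, 2 of them at 0, and at 0 in all 7 schizophrenia samples, at least 256-fold lower against a floor of 3 counts over the group (0.00608 CPM). LRRC28 isoform PB.34761.99 stood at 2.11 ± 1.66 CPM in controls, 3 of them at 0, and at 0 in all 7 schizophrenia samples, at least 348-fold lower. Both fold bounds treat an estimated 0 as no reads. They leave out isoform assignment and the spread between samples, and do not bound a group difference.

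None of the 39598 isoforms tested passed edgeR's quasi-likelihood test (0 called, 2120 at an unadjusted p under 0.05, of which 1028 higher and 1092 lower, smallest adjusted p 0.899). DESeq2 called 31 isoforms (7 higher, 24 lower), and limma-voom called 0 (2671 at an unadjusted p under 0.05). The smallest DESeq2 adjusted p was 4.38e-07, for the TIAL1 isoform named above. The named isoforms of LRRC28, MRFAP1, CAPZA1, BCAN, SDF4, RAPGEF5, RINT1 and HSD17B4 were also among the DESeq2 calls, so their status depends on the test. DESeq2 was not tried on simulated counts. Floors, and the Wilson intervals of shares given further below, rest on read counts and treat reads as independent. Reads amplified by PCR without molecular identifiers are not independent molecules, so these values may understate even counting error. The intervals of list means come instead from the exact permutation test and reflect the spread between samples.

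Isoform usage, the share of a gene's count that each isoform takes, was called different in 14 of 7762 genes with at least 2 tested isoforms. In 9 of them the isoform with the smallest p was present in part of the controls and at 0 in all 7 schizophrenia samples. DLAT isoform PB.27982.133, of a pyruvate dehydrogenase subunit gene, took 12.2% ± 10.5 of the gene's count in 11 controls and 0% in schizophrenia. There 3 counts of 40866 would be 0.00734%, at least 1664-fold lower by counting error alone. The isoform was at 0 in 11 of 18 samples, so some controls were at 0 too. Such fold bounds, here and below, leave out isoform assignment and the spread between samples, and do not bound a group difference. LRRC28 isoform PB.34761.99 took 7.93% ± 6.23 against 0% (at least 321-fold lower), and TIAL1 isoform PB.25937.111, of an RNA-binding protein gene, 2.65% ± 1.98 against 0% (at least 252-fold). NDRG4 isoform PB.35881.466 took 3.78% ± 3.77 in controls and 0.0873% ± 0.185 in schizophrenia, and SQSTM1 isoform PB.15140.186, of the autophagy receptor gene for p62, 3.68% ± 3.45 and 0.120% ± 0.317.

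In the other genes, isoforms at 0% in schizophrenia took 11.6% ± 12.5 of ZNF616 in 11 controls (at least 144-fold lower in schizophrenia), 6.56% ± 7.22 of CREB1, an activity-regulated transcription factor gene (at least 161-fold), 3.26% ± 2.94 of HLA-C (at least 985-fold), 2.63% ± 3.03 of HDLBP (at least 1485-fold), 1.83% ± 1.79 of CIRBP (at least 888-fold) and 1.67% ± 2.43 of ARHGEF3 (at least 393-fold). HLA-C belongs to a polymorphic family of near-identical genes, so its isoform counts are uncertain. THY1 isoform PB.28158.92 took 7.498% ± 13.4 in 11 controls and 0.214% ± 0.242 in 7 schizophrenia samples, and HS2ST1 isoform PB.1728.20 1.86% ± 3.57 and 0.0214% ± 0.0375. Without control 6 these share differences shrank from -1.84 to -0.889 percentage points for HS2ST1 and from -7.28 to -4.56 for THY1, and without control 5 that of ARHGEF3 from -1.67 to -1.07, and each call was lost. For HS2ST1 and ARHGEF3 the low-count filter then removed the isoform. VSNL1 isoform PB.4212.97, of a neuronal calcium sensor gene, was the only one of the 14 with a higher share in schizophrenia, at 0.549% ± 1.05 against 7.09% ± 17.7. That value rests on schizophrenia 7, at 47.3%, without which the share difference was -0.162 percentage points and the call was lost.

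These calls come from edgeR's diffSpliceDGE with Simes p-values per gene, adjusted by Benjamini-Hochberg (adjusted p from 2.09e-06 for DLAT to 0.0163 for THY1; 162 genes at an unadjusted p under 0.05). On simulated data the same test made 74 false calls among 83, and 0 of the 14 share differences passed an exact permutation test after adjustment (smallest adjusted p 0.0502, for LRRC28 and TIAL1). The shares themselves were called in 0 genes by limma on log2 shares (592 at an unadjusted p under 0.05) and in 0 by a quasi-likelihood test with the gene total as offset (384), and limma's diffSplice called 188 genes, 3 of the 14 among them. NDRG4, SQSTM1, LRRC28 and TIAL1 stayed called with any 1 sample left out, while each of the other 10 lost its call without at least 1 sample, and the number called lay between 5 and 97. In DLAT, CIRBP, HDLBP, HLA-C, HS2ST1, ZNF616, ARHGEF3 and CREB1 the leading isoform had 10 counts in only 7 controls and 0 schizophrenia samples. Without 1 of those controls the low-count filter removed the isoform, so such losses do not test the stability of the share difference. None of NDRG4, SQSTM1, LRRC28 and TIAL1 held in every setting: NDRG4 was at an adjusted p of 0.0958 with surrogate variables and 0.783 with the gene-level F test, SQSTM1 at 0.0786 and TIAL1 at 0.0514 with the F test, and LRRC28 at 0.5002 with diffSplice. With the offset test they were far from the threshold, at adjusted p of 0.9998 (NDRG4), 0.945 (SQSTM1), 0.918 (LRRC28) and 0.918 (TIAL1). The expression of none of the 14 genes passed the gene test, as for DLAT (log2 fold change -0.081, adjusted p 0.752) and TIAL1 (-0.025, 0.906). In GENCODE 29 on GRCh38, matched by symbol, NDRG4 lies on chromosome 16 (58462846 to 58513628), SQSTM1 on chromosome 5 (179806398 to 179838078), LRRC28 on chromosome 15 (99251362 to 99390729) and TIAL1 on chromosome 10 (119571802 to 119597029), and which exons distinguish the isoforms was not analysed here.

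Among the isoforms with the largest share change in these genes, LRRC28 isoform PB.34761.75 went the other way from PB.34761.99, at 1.87% ± 4.20 in 11 controls and 9.85% ± 4.69 in 7 schizophrenia samples (adjusted exact permutation p 0.0330). It was picked for the size of its change, so this p is too small.

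**Figure D3:**
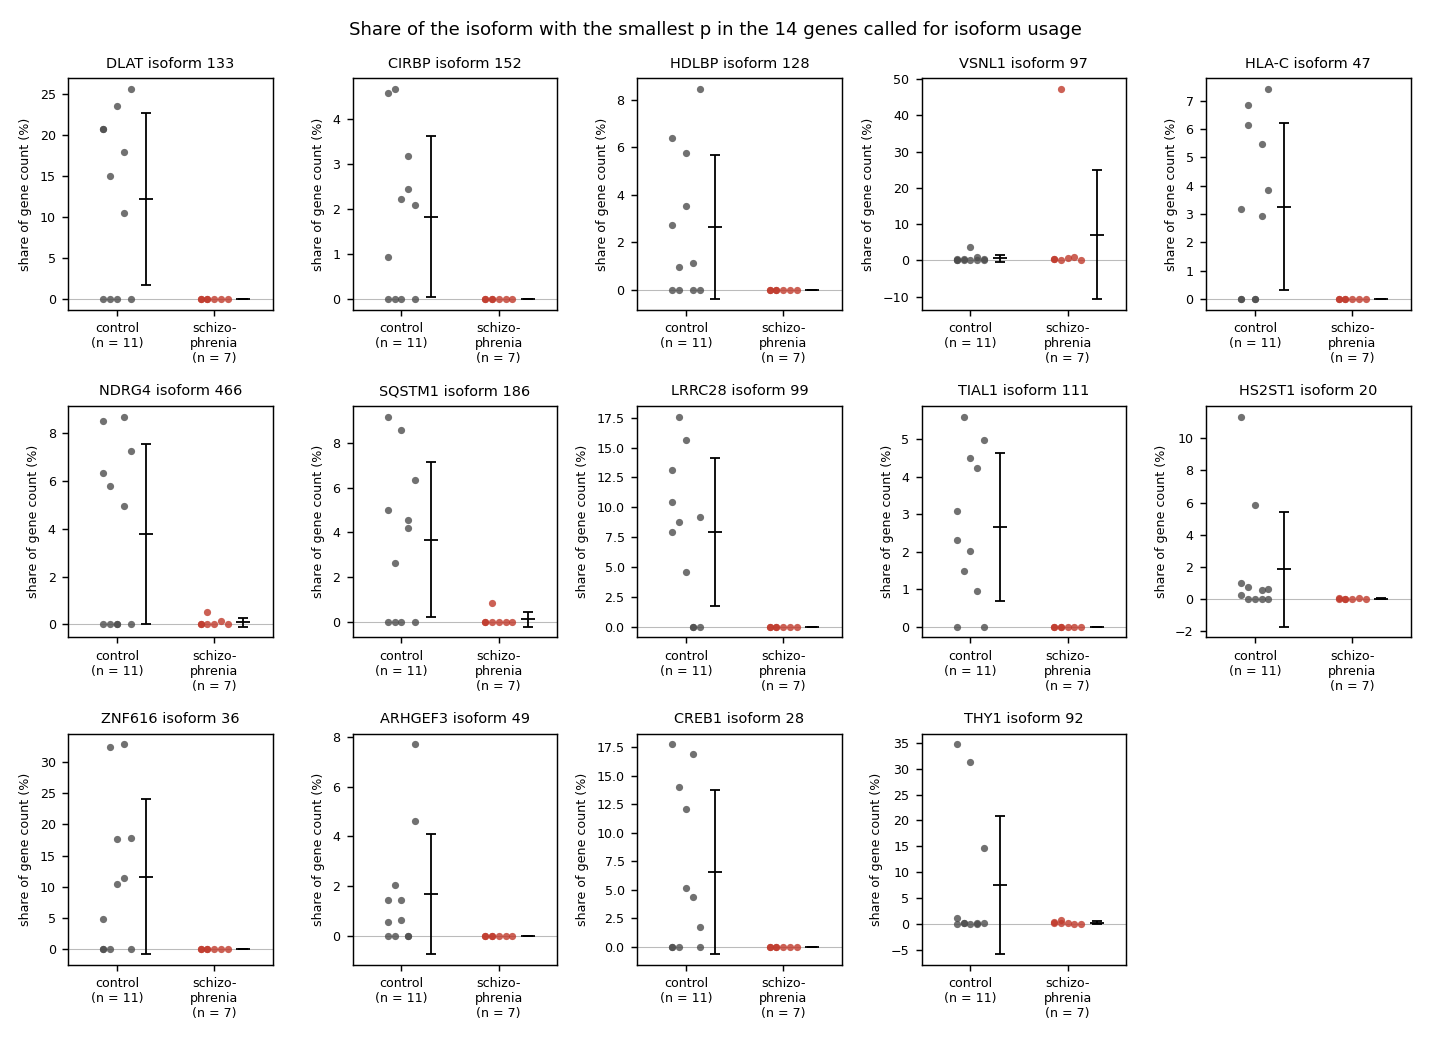
Share of the gene's count in percent (vertical axes, scaled per gene) taken by the isoform with the smallest p in each of the 14 genes called for isoform usage, in 11 control (grey) and 7 schizophrenia (red) samples; dots are samples, and bars the mean ± SD, which can extend below 0. Most isoforms were at 0 in every schizophrenia sample and in part of the controls, and the share of 47.3% for VSNL1 belongs to 1 sample.

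No synaptic or other list held any of the 14 genes. Of 25 presynaptic genes tested for isoform usage 3 were at an unadjusted p under 0.05 (0.522 by chance), among them DNM1, a dynamin gene of vesicle endocytosis (adjusted p 0.542 over all genes and 0.0801 adjusted over the list alone). Of 27 postsynaptic genes 2 were, with the glutamate receptor gene GRIA2 at 0.352 over all genes and 0.0401 adjusted over the list alone. PFKP, a phosphofructokinase gene, stood at 0.129 and 0.00506 adjusted over the list alone, ENO1 at 0.699 and 0.0382, and HERC1 at 0.751 and 0.0331, all from diffSpliceDGE. The values over a list alone are for leading members and are not adjusted over the 23 lists. On simulated data diffSpliceDGE made 74 false calls among 83, so they are no evidence for a list. After adjustment, Fisher's exact test found 0 of 23 lists enriched for the called genes, which was fixed because no list held any. For genes at an unadjusted p under 0.05 it also found 0 after adjustment. There the unadjusted Fisher p was 0.00409 for glycolysis (adjusted 0.0941) and 0.0147 for presynaptic genes. It was 0.0219 for cytoskeleton and axon genes and 0.0290 for excitatory neuron markers (adjusted 0.167 for each of these 3 lists). Ribosomal protein genes ranked later by isoform usage p than genes matched on isoform number and expression (mean rank at 76.8% of the list, 20 genes, permutation p 0.0001, the smallest these permutations can give, adjusted p 0.0023), and the other 22 lists did not pass this test. The permutation takes genes as independent, while expression of the ribosomal genes was correlated (estimated correlation 0.802), so its p may be too small. The ranks also rest on diffSpliceDGE and on uncertain counts of these genes.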

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

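The test of VSNL1 transcription below was read against a bound set only after its value was seen, and the other test of this part was written beforehand. Of 177 values examined among the 7 schizophrenia samples, 7 had 1 sample far from the rest, and chance gives about 1 in 20.

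VSNL1 isoform PB.4212.97 took 47.3% of the gene's count in schizophrenia 7 (37086 of 78428 counts, 95% Wilson interval 46.9% to 47.6%), against 0.0749% to 0.807% in the other 6 samples. More VSNL1 transcription in that library is argued against by its gene total of 1720 CPM, below the 1992 to 2377 CPM of the other schizophrenia samples. Unusual quality of the library as a whole may contribute: it held 28 isoforms at a share at least 30 points above every other library, against at most 21 in any other library and a median of 6.5 over all 18. It also had the lowest total count (45866112). Whether isoform assignment or biology of the donor gave the value stays open, and no biological explanation other than more transcription was tested.

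BDNF, a neurotrophin gene, stood at 3.80 log2 CPM in schizophrenia 7, below the other schizophrenia samples (4.76 to 5.12). CD59, a complement inhibitor gene, stood at 8.70 log2 CPM in the same sample, above the others (8.45 to 8.50). SQSTM1 isoform PB.15140.186 took 0.839% in schizophrenia 7 (135 of 16089 counts, 95% Wilson interval 0.709% to 0.992%) and 0% in the other 6. DST, a cytoskeletal linker gene, stood at 3.64 log2 CPM in schizophrenia 3, below the others (4.62 to 5.19). CACNA2D3 stood at 6.94 log2 CPM in schizophrenia 2, above the others (6.22 to 6.47). NDRG4 isoform PB.35881.466 took 0.494% in schizophrenia 2 (897 of 181659 counts, 95% Wilson interval 0.463% to 0.527%), against 0% to 0.118% in the others.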

How the results depend on the processing

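Alternatives chosen after seeing the data were the offset usage test, the filter on isoforms seen in 16 of 18 samples, the permutation tests of list means and shares, the principal component, GC and length covariates, and list means and shares without each sample. Apart from losses that follow from a filter, named below, the causes of the differences between settings were not tested. The count of 0 genes was the same under all 9 other settings (539 to 1471 genes at an unadjusted p under 0.05) and without each sample. The count of 0 isoforms held in all settings except DESeq2, with 31, and no list was enriched for isoform usage in either alternative.

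The 14 genes called for isoform usage became 188 with limma's diffSplice (3 of the 14 kept), 0 with limma on shares, 0 with the offset test, 26 with a mean count of 10 and a mean share of 5% (2 kept), 736 with no filter (13 kept), 56 with surrogate variables (9 kept), 5 with isoforms seen in 16 of 18 samples (2 kept), 14 with RLE (14 kept) and 15 with the gene-level F test (8 kept). The filter on 16 of 18 samples removes any isoform at 0 in at least 3 samples. As 12 of the 14 leading isoforms were, their removal was fixed in advance and does not test their calls. Leaving out 1 sample gave 5 to 97 genes: 6, 8, 5, 7, 8 and 8 without control 3, 4, 5, 6, 9 and 11, and 56, 97, 51, 47, 57, 88 and 51 without schizophrenia 1 to 7. The low-count filter let in more isoforms without a schizophrenia sample (40017 to 40121, against 39598 with all samples) and fewer without a control (39206 to 39387). The higher counts thus do not measure dependence on the sample alone, and how many calls came from added isoforms was not tested. Calls were lost without control 2, 3, 4, 5, 6, 9 or 11 for DLAT and CIRBP, control 3, 5, 6, 7, 8, 9 or 11 for HDLBP, control 2, 4, 5, 6, 7, 9 or 10 for HLA-C, control 1, 2, 3, 4, 5, 6 or 11 for HS2ST1, control 2, 3, 4, 5, 8, 9 or 11 for ZNF616, control 3, 4, 5, 6, 7, 8 or 9 for CREB1, control 3, 5 or 6 for THY1, and control 2, 3, 5, 6, 8, 10 or 11 or schizophrenia 1, 3, 4, 5, 6 or 7 for ARHGEF3. Except for THY1, the leading isoform of these genes had 10 counts in only 7 controls and 0 schizophrenia samples. The losses without a control thus follow from the low-count filter, which removed the isoform, and do not measure dependence of the share on that control.

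The 3 gene lists past camera became 0 with an estimated correlation, 0 with fry and 0 with exact permutation of list means, and 8 with GC and length slopes as covariates, among them the ribosomal list (adjusted p 0.0128) but not the astrocyte (0.751) or channel list (0.559). The other 7 were immediate early, microglia, postsynaptic, presynaptic, splicing and white matter lists (higher) and the myelin list (lower). With these covariates and an estimated correlation 0 lists passed (adjusted p 0.801 for each of the 8). Leaving out 1 sample gave 1 to 5 lists (1 without schizophrenia 1 or 3, 5 without schizophrenia 4), and the ribosomal list passed in 18 of 18 such runs, the astrocyte list in 12 and the channel list in 14.

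The replicate number in the titles was also fitted as a replicate block. It gave 0 genes, 0 isoforms, 64 isoform usage genes (8 of the 14 kept) and 3 lists. Same-numbered samples correlated at -0.43 to 0.47, and only number 6 correlated best with its own number. Expression thus showed no pairing by number, which cannot exclude that samples were matched by number on other traits. Under the block the log2 fold changes of CD59 (0.037), SERPINA3 (0.62) and TREM2 (-0.20) turned, and with sample quality weights that of SERPINA3 (0.037).

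Of the results that turned, only VSNL1 had been called, by isoform usage. CSF3R turned to 0.0078 with surrogate variables. With GC and length slopes as covariates CSF3R (0.27), CLU (-0.068), PDGFRB (-0.050), FLT1 (0.13), MT1G (-0.15), CD68 (0.26), C1QC (0.33) and CHRM3 (0.022) turned. Without 1 sample, log2 fold changes spanned 0 for CSF3R (-0.24 to 0.16), CD59 (-0.088 to 0.037), SERPINA3 (-5.02 to 1.05), TREM2 (-0.14 to 0.41), CD68 (-0.43 to 0.0035), C1QC (-0.38 to 0.020), SPI1 (-0.021 to 0.27), NEAT1 (-0.018 to 0.23), ABCC9 (-0.031 to 0.38) and MT1G (-0.0083 to 0.32). List mean differences spanned 0 for endothelial (-0.083 to 0.072), excitatory (-0.024 to 0.061) and inhibitory neuron (-0.038 to 0.097), myelin (-0.32 to 0.060), microglia (-0.22 to 0.22), monoamine (-0.074 to 0.033), glycolysis (-0.0063 to 0.023), complement (-0.15 to 0.0013), heat shock (-0.084 to 0.024), inflammation (-0.27 to 0.057), nuclear RNA (-0.039 to 0.10), presynaptic (-0.076 to 0.0051) and postsynaptic genes (-0.088 to 0.0097). The VSNL1 share difference ran from -0.162 (without schizophrenia 7, where the call was lost) to 7.71 percentage points. Depth limits isoforms near a floor of 3 counts, and 10444 isoforms had no count at all.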

Other observations

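Chosen only after the result was seen were the test of isoforms at 0, the test of list means between the diagnoses and the slopes as covariates, while the GC and length tests were added after the leading genes were seen and their bounds set before their values were computed.

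Gene lists differed in their range over the samples, which was described and not tested. The mean of the 19 myelin genes ranged from 5.36 to 8.31 log2 CPM over the 18 samples, that of 9 microglial markers from 0.917 to 3.74 and that of 18 astrocyte markers from 7.42 to 9.62. White matter, subplate and meningeal markers ranged from 2.28 to 5.24. Inflammation genes ranged from 1.77 to 4.48 and immediate early genes from 4.23 to 6.15. Oligodendrocyte precursor markers ranged from 5.15 to 5.96, the 16 excitatory neuron markers from 6.49 to 7.04, and the 17 inhibitory neuron markers from 4.79 to 5.72. The 19 glycolysis genes lay between 8.69 and 8.91, the 38 oxidative phosphorylation genes between 7.47 and 7.79, and the 37 splicing regulators between 6.75 and 6.92.

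Synaptic genes differed in how their counts were divided among isoforms. Isoform numbers here are entries in the table, which also holds isoforms at 0 in every sample, so they do not count detected isoforms. DLGAP1, a postsynaptic scaffold gene, had 41 isoforms with its main one at 26.5% of the count, SNAP91 36 at 21.3%, DNM1 26 at 35.4% and SNAP25 21 at 39.3%. SLC17A7, CACNG3 and GRM5 each had 1 isoform in the table, and VAMP2 had 2 with 1 of them at 100%. Whether synaptic genes carry more isoforms than others of their expression was left open: the 60 genes of both synaptic lists had a mean of 9.92 isoforms, against a median of 8.92 in 10000 matched lists (95% of them between 6.87 and 11.7, one-sided permutation p 0.228) and 5.16 over all genes.

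The 14 isoform usage genes are a pattern that chance could give: 12 of 100 splits of the 18 samples, the real one included, called as many, and another split called 64. Of the 14 leading isoforms 12 stood at 0 in at least 3 samples, against 23.02% of tested isoforms (one-sided Fisher's exact p 1.24e-06), but 9 of them had already been seen at 0 in all 7 schizophrenia samples, so this p says nothing on why they were called. Hidden structure cannot be told apart from the diagnosis, as 9 of the 14 stayed called with surrogate variables, between the bounds set beforehand. Isoforms at 0 in all 7 schizophrenia samples and at 10 counts in at least 7 controls numbered 10, against a median of 8 and a highest of 40 in other splits, and 24 of 100 splits had as many. A difference between the diagnoses stays open.

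Gene fold changes followed transcript GC content, with a Spearman correlation of 0.404 across 10544 genes, which are not independent replicates. GC slopes of the libraries were -0.0223 ± 0.0544 in 11 controls and 0.0350 ± 0.0541 in 7 schizophrenia samples (exact permutation p 0.0449, 1 of 2 slope tests, not adjusted), so GC bias may contribute. Without 1 sample p ran from 0.0191 to 0.120, at 0.05 or more without control 3, 5, 6, 8 or 11 (0.0729, 0.0685, 0.0732, 0.0558 and 0.0724) and without schizophrenia 3, 4 or 7 (0.0767, 0.0878 and 0.120). A correlation of -0.0858 across genes, within the bound set beforehand, counts against transcript length (exact permutation p of the length slopes 0.192). It cannot exclude length, because lengths were medians over the annotated transcripts of a gene, not those of the isoforms measured. Genes at an unadjusted p under 0.05 had medians of 907 bases (higher) and 1211 (lower), against 1004 over all genes. RNA quality or cell mixture that shifts GC-rich genes stays open, and a difference between the diagnoses too.

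Counts from other splits stood beside the group comparison as follows. For 0 genes and for 0 isoforms by edgeR (973 and 2120 at an unadjusted p under 0.05; DESeq2 0 and 31), all 100 of 100 splits had as many, which a count of 0 ensures, with a highest of 2 genes and 1 isoform. As many as 973 genes at an unadjusted p under 0.05 were found in 12 of 100 splits (highest other 1579, median 387), so chance could not be excluded. The 3 lists past camera were matched in 93 of 100 splits, with a highest of 19 lists and a median of 8, 2 of the 3 stayed with surrogate variables, and the smallest adjusted exact permutation p of their means was 0.850.

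The main axis of the libraries was shared by expression and isoform shares. The first principal component held 25.8% of the variance of expression and 24.4% of that of 23849 isoform shares, and both components correlated (Pearson's r 0.663, permutation p 0.00291; Spearman's rho 0.641, p 0.00504; r 0.532 without the 2 samples farthest from the median, p 0.0344). It did not separate the groups in expression (exact permutation p 0.556) or in shares (0.0551). Of 3 relations of the expression component, that with the length slope had r -0.798 (permutation p 6e-05, adjusted 0.00018; rho -0.835, p 8e-05; r -0.731 without 2 samples), that with the GC slope r 0.708 (p 0.00084, adjusted 0.00126; rho 0.604, p 0.00887; r 0.516 without 2 samples) and that with the total count r -0.338 (p 0.173, adjusted 0.173; rho -0.183, p 0.466). The component also followed the list means of postsynaptic genes (r -0.897), excitatory neuron markers (-0.872), voltage-gated channels (-0.848), myelin genes (0.730) and astrocyte markers (0.707). The slopes and list means come from the same log2 CPM values as the component. These correlations therefore describe the axis and are not independent evidence for a source. A technical source such as RNA fragmentation and the mixture of neurons and glia in the tissue could each underlie the component, and they were not told apart.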
